A study of Populus tremula x Populus alba with 3 samples.

How the data were processed

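RNA was measured by sequencing in shoot apices of hybrid poplar, a cross of Populus tremula and Populus alba, with all plants of 1 clone. There were 3 libraries, 1 from wild type and 1 from each of 2 lines that over-express CsDML, all taken after 28 days in SD. The labels spell out neither abbreviation; from general knowledge of the study, SD is read here as short days, which induce growth arrest and bud set in poplar, and CsDML as a DEMETER-like gene of chestnut. Per the labels' protocols the libraries were made from total RNA with a directional kit, in which reads keep their strand.

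The submitters' processing notes name FastQC, TopHat and edgeR, without versions. The genome build, the annotation, the read counter and the kind of edgeR test are not given in the sources used here. The deposited data analysed here are the authors' own comparison of the over-expressing lines with wild type. Per the file headers, each gene has a log2 fold change, a mean level on the log2 CPM scale (CPM, read counts scaled to the library total), an unadjusted p-value and an FDR-adjusted p-value. The base of the logarithm was read as 2 from the column names, which are those of edgeR per the submitters' processing notes; the authors' deposited table does not state it. Each gene has 1 value for the whole comparison, so the table gives no level per library or per line, no standard error and no total count. The depth of the libraries is therefore unknown, and intervals that need a depth are not given. Of the rows, 288 carry an Arabidopsis best hit, 142 a best-hit gene name and 256 a description. Genes are named below by these best hits. Chromosomes are read from the gene IDs (Potri.009G for chromosome 9, Potri.T for unplaced sequence), and no coordinates are given because no genome was used here.

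The number of genes the authors tested was recovered from the p-value, its rank and the adjusted p-value of each row, and came to 41335. Benjamini-Hochberg values recomputed over that number matched the deposited adjusted p-value in 318 of 318 rows, within a relative tolerance of 1e-06. The table thus holds each of the 41335 tests with an adjusted p-value under 0.1. Wild type had 1 library, so the difference has no replicate check on that side, and the p-values rest on the spread the authors assumed or took from the other libraries. No test of a fold change was added here. The 3 planned comparisons that need a value per line could not be made. They are the genes with the same sign in both lines, the difference between the lines and the correlation of their changes.

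Genes with an adjusted p-value under 0.05 are described as having risen or fallen, and those between 0.05 and 0.1 as listed higher or lower. Before the data were examined, 26 gene lists were fixed. They covered DNA methylation, flavonoids, phenylpropanoids and lignin, the cell cycle, photosynthesis, cold and dehydration, heat shock, 5 hormones, flowering and bud set, the clock, the cell wall, xylem, phloem, meristem, cuticle, defence, redox, carbohydrates, storage proteins, transcription factors, organelle and ribosomal genes, and transposons. Members were taken by pattern in the description or name, by gene symbol or by Arabidopsis ID. For lists of at least 3 members, the share higher and the median log2 fold change were placed among 10000 random lists of the same size, drawn from the table and matched on 4 quartiles of mean level. These percentiles describe the table and are not p-values, since genes are not replicates. The share of higher genes per chromosome, a test chosen after the table was seen, was set against 10000 random assignments of direction to the rows, over the whole table and, for chromosome 9, also within the 4 quartiles of mean level.

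The genes named were fixed by rule before the data were examined. They are the members of the DNA methylation list, the 10 genes with the largest absolute log2 fold change in each direction among those with an adjusted p-value under 0.05 and a level of at least 1 CPM, and up to 4 members of each list with the largest change. The level of the higher group was worked out from the mean level and the fold for 2 over-expressing libraries and 1 wild-type library. At most 2 IDs per direction without a name or description are printed. Genes named outside this rule are said to be chosen after their values were seen. Members of a list can fall outside what its name says, and such members are described where they are named. Alternatives were a threshold of 0.01 or 0.1, a minimum absolute log2 fold change of 1, a minimum mean level of 1 on the log2 CPM scale, and list members by ID or symbol only.

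The scripts were tested on simulated data. The number of tests was recovered as 20000 of 20000 simulated. A list of 15 members set higher reached percentile 100, and 25 of 400 random lists passed the 95th percentile. An excess of 15 higher rows on chromosome 9 was found in 50 of 50 simulations, and 3 of 50 with shuffled directions gave an excess on some chromosome. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.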

Results

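Gene expression was compared between shoot apices of wild-type hybrid poplar and of 2 lines over-expressing CsDML, read here as a DEMETER-like gene of chestnut, after 28 days in SD, read as short days. DEMETER-like proteins are DNA glycosylases that remove methylated cytosine. The comparison asked which transcripts differ at this stage of bud development when such a demethylase is over-expressed. Wild type was represented by 1 library and the over-expressing lines by 1 library each, which the authors joined in 1 comparison. The p-values below therefore do not measure how much wild-type apices vary, and values per line were not used here.

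Of the 41335 genes tested, 318 (0.769%) are in the authors' deposited table, 79 higher and 239 lower in the over-expressors. At an adjusted p under 0.05 the authors' deposited table holds 203 genes, of which 43 rose and 160 fell. Most changes were moderate. In the authors' deposited table the median higher gene had a log2 fold change of 1.56 (2.94-fold) and the median lower gene one of -1.21 (2.31-fold lower). Large changes were more frequent among higher genes, with 35 of 79 at a log2 fold change of 2 or more against 26 of 239 lower genes at -2 or less in the authors' deposited table. Of the 35, 14 had fitted values above 6 at a mean level under 3 on the log2 CPM scale, which are not measured ratios (below). Another 7 lie in the 2 runs of neighbouring IDs that hold the plastid-encoded best hits (below). Among the lower genes, 3 had fitted values below -6. The groups also differed in annotation, since 22 higher genes (27.8%) and 8 lower genes (3.35%) had no Arabidopsis best hit there. Of these 22, 6 have such fitted values and 5 lie in the 2 runs.

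The smallest change in the authors' deposited table was 0.857 on the log2 scale, and the limit depended on level. Among genes with a mean level of 2 to 3 on the log2 CPM scale the smallest listed change was 1.30 for lower genes and 1.93 for higher genes. At 6 to 7 the smallest were 0.857 and 0.93. The limit thus also differed by direction, and smaller differences at these levels are not listed, which does not show that they were absent. The deposited p-values followed from fold and level almost alone. The variance implied by each p was predicted from the level of each group, worked out from mean level and fold. The R2 was 0.994 over 228 lower genes with a mean level above 1 on the log2 CPM scale. It was 1.00 over 53 higher genes with a log2 fold change under 3. Fold enters both sides of this fit, and only listed genes are in it. In addition, 10 genes shared their exact p with another gene. For the genes fitted, the authors' deposited p-values thus seem to carry little information on how much a single gene varied between libraries.

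**Figure D1:**
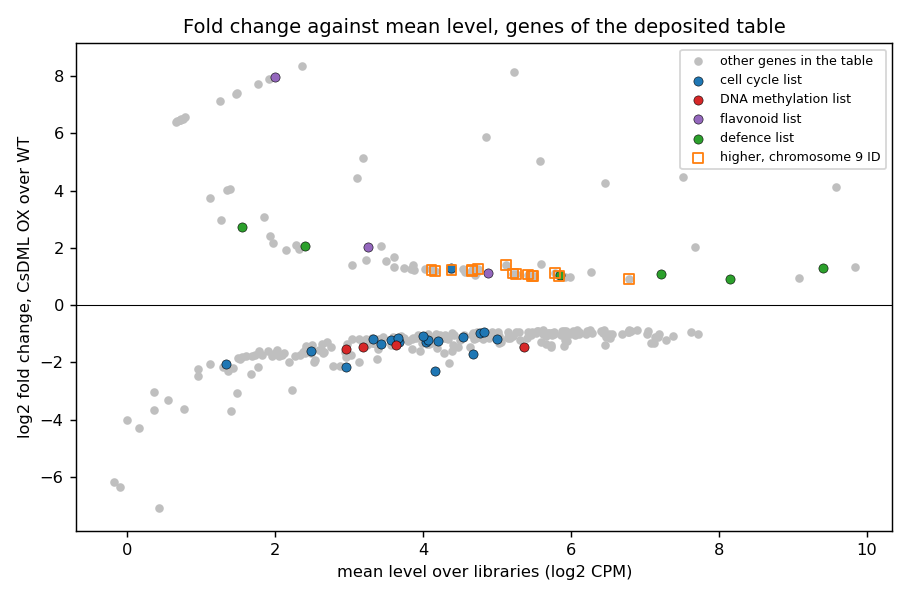
Log2 fold change of CsDML over-expressors over wild type (vertical axis) against mean level in log2 CPM (horizontal axis) for the 318 genes of the authors' deposited table, 1 point per gene, with members of 4 lists coloured and the 15 higher genes with chromosome 9 IDs boxed. The listed changes approach 0.857 at high levels, and 14 higher genes at the upper left lie on a single curve of fold against level.

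The listed genes that maintain or remove DNA methylation were lower. All 4 listed members of the DNA methylation list fell in the authors' deposited table, with a median log2 fold change of -1.46 (2.75-fold lower). They were 2 homologues of MET1, the maintenance methyltransferase for CG sites (Potri.004G134000, -1.54, adjusted p 0.00749; Potri.T046100, -1.47, adjusted p 0.00741, per the authors' deposited table). CMT3, a chromomethylase that methylates CHG sites, fell by 1.45 on the log2 scale in the authors' deposited table (Potri.001G009600, adjusted p 6.07e-05). A poplar gene whose best hit is DEMETER, which removes methylcytosine, fell by 1.38 in the authors' deposited table (Potri.010G234400, adjusted p 0.00733). This single row does not stand for all demethylase genes of poplar. The median of the list was at percentile 4.50 of random lists of the table. Its share of higher genes, 0 of 4, was at percentile 19.6, because 75.2% of all listed genes were lower. The 2 MET1 rows have the same best hit, and how reads were divided between such copies is not given in the sources used here. No row of the authors' deposited table carries the chestnut transgene, so its level could not be checked.

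Cell cycle genes were mostly lower. Of 19 listed members, 18 were lower and 1 higher in the authors' deposited table, and at an adjusted p under 0.05 12 fell and 1 rose. The median log2 fold change was -1.22. The 2 phragmoplast orienting kinesins, motors that guide the new cell plate, fell to 4.94-fold lower (POK2, Potri.004G145800, adjusted p 5.80e-11) and 4.44-fold lower (POK1, Potri.010G153000, adjusted p 7.95e-06) in the authors' deposited table. A kinesin with a di-glucose binding domain was listed at -2.04 with an adjusted p of 0.0521 in the authors' deposited table (Potri.001G436200). A histone gene whose best hit encodes histone H4 fell by 1.71 in the authors' deposited table (Potri.005G115300, adjusted p 2.54e-06). Another gene with the same best hit rose by 1.29 (Potri.018G093000, adjusted p 0.0277), the exception in the authors' deposited table, and is named after its value was seen. The share of higher genes in this list was at percentile 2.71 of random lists and its median at percentile 11.5. Beside these lower genes, the list that also serves as a marker of leaf tissue, photosynthesis, had 3 of 3 rows higher. Only LHCA3 had an adjusted p under 0.05. The others, PSAO and FD3, have chromosome 9 IDs, and FD3 is no leaf marker (below), so the list gives little sign of leaf tissue. The list that serves as a sign of RNA quality, organelle and ribosome genes, had 2 of 2 higher.

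Of the flavonoid list, TT7 rose. All 3 listed members were higher in the authors' deposited table, 2 of them at an adjusted p under 0.05, and the share was at percentile 99.3 of random lists, but 1 of those 2 is a doubtful member. TT7, the flavonoid 3'-hydroxylase, rose by 2.03 on the log2 scale, or 4.07-fold, in the authors' deposited table (Potri.003G066800, adjusted p 0.00195). A gene named DFR by its best hit rose with a fitted log2 fold change of 7.97 in the authors' deposited table (Potri.T168400, adjusted p 5.48e-06). Its best hit, AT2G45400, is not the DFR gene of the fixed list, AT5G42800. Chalcone synthase, the entry enzyme of the pathway, was listed at 1.11 with an adjusted p of 0.0612 in the authors' deposited table (Potri.001G051500). Both phenylpropanoid and lignin rows of the authors' deposited table were taken in by a shared alias, CCR1, and their best hit SDG8 is a histone methyltransferase (-1.21, adjusted p 0.00432, and -0.93, adjusted p 0.0745).

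Genes taken in by the defence, cuticle and photosynthesis lists were also higher. All 6 defence members were higher in the authors' deposited table, 3 at an adjusted p under 0.05, with the share at percentile 99.99. The list can miss related genes of either direction, so the direction and the percentile hold for the rows it took in. A Kunitz-type protease inhibitor at a mean level of 9.40 on the log2 CPM scale rose by 1.30 in the authors' deposited table (Potri.004G067800, adjusted p 0.00102). A thaumatin-like gene rose by 2.06 (Potri.001G221500, adjusted p 0.0256) and a chitinase by 1.09 (Potri.019G093900, adjusted p 0.0208) in the authors' deposited table. The RPS2-like resistance gene was listed at 2.72 with an adjusted p of 0.0605 in the authors' deposited table. Of the 3 cuticle and lipid members, all higher (percentile 98.9), 2 GDSL lipases rose by 2.40 and 2.09 in the authors' deposited table (adjusted p 0.0321 and 0.0342), and LTP1, a lipid transfer protein, was listed at 1.31 (adjusted p 0.0566). The photosynthesis list had 3 of 3 members higher (percentile 99.3), 1 of them at an adjusted p under 0.05. LHCA3, a light-harvesting protein of photosystem I, rose by 1.43 in the authors' deposited table (Potri.014G198400, adjusted p 0.00135). PSAO was listed at 1.08 and ferredoxin FD3, a root-type ferredoxin and no leaf marker, at 0.93 in the authors' deposited table (adjusted p 0.0558 and 0.0982).

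Genes taken in as transcription factors were lower. All 18 members of the transcription factor list were lower in the authors' deposited table, 13 at an adjusted p under 0.05, with the share of higher genes at percentile 0.285. The median log2 fold change, -1.10, was at percentile 12.05. RRTF1, a redox-responsive factor of the ERF family, fell by 3.66 and an integrase-type DNA-binding gene by 3.31 in the authors' deposited table (Potri.009G101900, adjusted p 0.0189; Potri.006G138700, adjusted p 0.0162). Their mean levels were low, 0.37 and 0.55 on the log2 CPM scale. A row described only as DNA binding was listed at -1.61 (Potri.008G097700, adjusted p 0.0828), and one described as an ATPase that binds transcription factors fell by 1.37 in the authors' deposited table (Potri.017G039100, adjusted p 0.000166). The list also took in genes of other functions, such as a DHHC-type zinc finger gene, a family of protein acyltransferases, listed at -1.24 in the authors' deposited table (Potri.003G160600, adjusted p 0.0610, named after its value was seen). It missed 2 higher RWP-RK regulators, listed at 7.89 (fitted) and 1.27 in the authors' deposited table (Potri.012G016800, adjusted p 8.35e-06; Potri.017G022000, adjusted p 0.0612, chosen after its value was seen), so the single direction and the percentiles hold for the rows the list took in.

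All 3 cold and dehydration members fell in the authors' deposited table, with a median log2 fold change of -1.99 at percentile 1.45. Their share of higher genes, 0 of 3, was at percentile 20.65. The median is the value of a row known only by its LEA family description, named below. Of the others, CBF2 has a fitted value and CBF5 matched by name alone, so the percentiles say little about cold genes. CBF2, a cold-response regulator, had a fitted value of -6.34 at a mean level of -0.09 on the log2 CPM scale in the authors' deposited table (Potri.001G110800, adjusted p 0.0188). A row described as of the LEA hydroxyproline-rich glycoprotein family fell by 1.99 there (Potri.009G158900, adjusted p 1.47e-05, authors' deposited table). That description is a family label and does not show a role in cold or dehydration. The remaining member, CBF5 (Potri.006G044100, -1.02, adjusted p 0.0201 in the authors' deposited table), matched by its name alone and encodes a homologue of NAP57, a protein of RNA modification. The auxin list took in 3 rows, all lower and 2 at an adjusted p under 0.05, of which 1 is an auxin gene. The auxin transport protein BIG fell by 1.34 in the authors' deposited table (Potri.017G101100, adjusted p 9.54e-05). The remaining rows, at -1.36 and -0.93 (adjusted p 0.00294 and 0.0626 in the authors' deposited table), were homologues of AUL1, an auxilin-like protein that entered through the wording of its description.

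Cell wall genes went both ways, with 4 of 14 listed members higher and 10 lower in the authors' deposited table (percentile 60.9 for the share higher). At an adjusted p under 0.05, 2 rose and 6 fell. Expansin A23, a wall-loosening protein, and the cellulose synthase-like gene CSLG3 had fitted log2 fold changes of 8.37 and 7.41 in the authors' deposited table (adjusted p 3.51e-08 and 0.000596). XTH23, a xyloglucan-modifying enzyme, had a fitted value of -7.10, and a pectin lyase-like gene fell by 2.12 in the authors' deposited table (adjusted p 9.54e-05 and 3.39e-05). Among heat shock and chaperone genes 1 of 4 was higher (percentile 56.7). A DnaJ-domain gene rose by 1.22 (Potri.009G131800, adjusted p 0.0314), while 2 rows with another DnaJ best hit fell by 1.42 and 1.17 in the authors' deposited table (adjusted p 4.57e-05 and 0.0170), and a prefoldin was listed lower (adjusted p 0.0510). Of 5 redox members 1 rose (TT7, above) and 1 fell, a glyoxalase at -1.15 (adjusted p 0.0218, the authors' deposited table; share higher at percentile 45.8). A glutaredoxin and MRP3, a transporter, were listed at -1.38 and -1.18 there (adjusted p 0.0780 and 0.0647, the authors' deposited table).

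Of the markers of other tissues, LHCA3, of the leaf-marker list above, rose, and XCP1, a xylem peptidase, fell by 1.75 (Potri.004G207600, adjusted p 0.0489) in the authors' deposited table. The meristem list had 2 rows, both homologues of HB-1, a homeobox gene of chromatin remodelling, listed at -0.91 and -0.87 in the authors' deposited table (adjusted p 0.0743 and 0.0955). SUS5, a sucrose synthase, fell by 1.68 in the authors' deposited table (Potri.017G139100, adjusted p 0.0292) and was the single row the carbohydrate list took in. GWD1, a starch dikinase that the list missed and that is named after its value was seen, fell by 1.24 in the authors' deposited table (Potri.008G188100, adjusted p 0.0188). The single row of the transposon list was the integrase-type DNA-binding gene named above, a relative of the ERF family and not a transposon. The organelle and ribosome rows, fixed as a sign of RNA quality, both had plastid-encoded best hits and rose, by 3.07 for ribosomal protein L16 (Potri.013G140500, adjusted p 0.0117) and by 2.05 for S19 (Potri.011G074200, adjusted p 4.16e-09) in the authors' deposited table. The other 8 lists took in no row of the authors' deposited table, namely abscisic acid, gibberellin, ethylene, cytokinin, flowering and bud set, clock, phloem and storage proteins. They can miss related genes. Named after their values were seen, the abscisic acid transporter ABCG40 fell by 1.75 (Potri.018G032900, adjusted p 0.0288), and ARIA, a partner of an abscisic acid factor, was listed at -1.89 (adjusted p 0.0582) in the authors' deposited table. The clock regulator TIC and a Frigida-like gene were listed at -0.93 and -1.09 in the authors' deposited table (adjusted p 0.0579 and 0.0745).

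**Figure D2:**
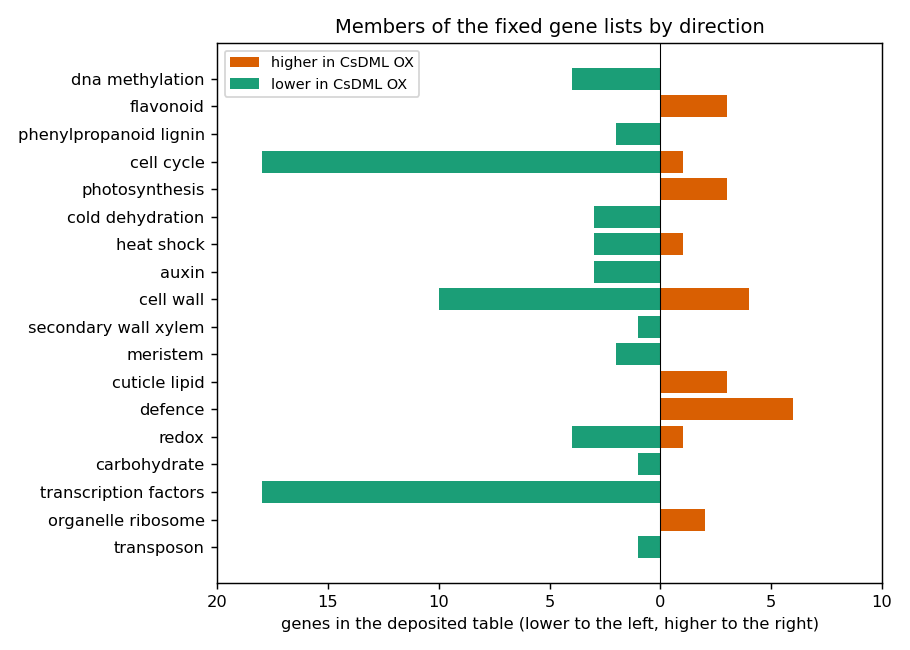
Number of members of each fixed gene list that are lower (bars to the left) or higher (bars to the right) in CsDML over-expressors among the 318 genes of the authors' deposited table. The cell cycle list has 18 lower and 1 higher, the transcription factor list 18 lower, and the defence list 6 higher; 8 lists with no member are left out.

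The 10 steepest rises at an adjusted p under 0.05 had fitted log2 fold changes of 5.13 to 8.37 in the authors' deposited table, and 6 of them had no name or description. Besides expansin A23, the DFR-named row and CSLG3 they included an RWP-RK domain gene at 7.89 in the authors' deposited table (Potri.012G016800, adjusted p 8.35e-06). Of the unnamed genes, Potri.001G412500 rose by 8.15 at a mean level of 5.23 on the log2 CPM scale (adjusted p 5.11e-34), and Potri.013G139800 rose by 5.88 (adjusted p 3.28e-26) in the authors' deposited table. Potri.013G139800 lies in the chromosome 13 run of neighbouring IDs that holds a plastid-encoded best hit (below). Another unnamed gene of the 10, at 5.13, lies there too. A log2 fold change above 6 was listed for 15 genes of the authors' deposited table, and 14 of them had a mean level under 3 and a fold that followed the level exactly in rank (Spearman's rho 1, across genes). Folds of that kind are set by the constant added to a group with almost no reads, so they are fitted values and not measured ratios. The same holds for the 3 genes below -6 in the authors' deposited table, XTH23, CBF2 and MIOX4 (-6.19, Potri.018G069700, adjusted p 0.0357), an oxygenase of inositol. The other steep decreases in the authors' deposited table included CML37, a calmodulin-like calcium sensor (-3.64, adjusted p 0.00144), and a DUF789 gene (-3.71, adjusted p 3.62e-06). RRTF1 and the integrase-type gene were among them. So were an ARM repeat gene (-3.06, adjusted p 2.87e-05), EXO, a growth-related gene (-2.97, adjusted p 1.37e-07), and 1 gene without a name. CML37, RRTF1, the integrase-type gene and the unnamed gene had mean levels under 1 on the log2 CPM scale.

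By gene ID, in a test chosen after the table was seen, higher genes were unevenly spread over the chromosomes. Chromosome 9 held 15 of the 79 higher genes (19.0%) but 6 of the 239 lower genes (2.51%) in the authors' deposited table. Its share of the table would give 5.22 higher genes. None of 10000 random assignments of direction gave as large an excess on any chromosome, and the most on chromosome 9 was 13. With directions reassigned within quartiles of mean level, 0 of 10000 gave as many on chromosome 9, and the most was 12. These 15 genes had log2 fold changes of 0.93 to 1.40 (1.90-fold to 2.63-fold), at mean levels of 4.11 to 6.78 on the log2 CPM scale in the authors' deposited table. At an adjusted p under 0.05, 7 of the 15 rose. They include PSAO, FD3 and the higher DnaJ-domain gene named above.

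**Figure D3:**
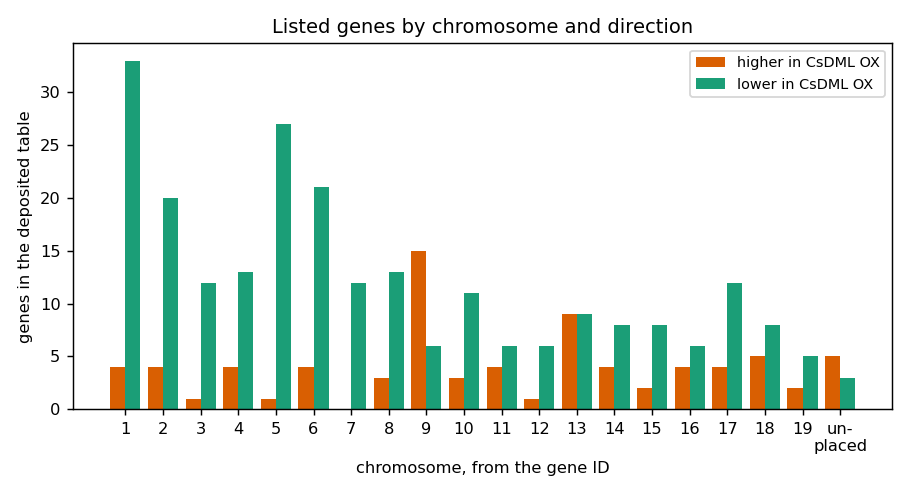
Number of genes of the authors' deposited table (vertical axis) that are higher or lower in CsDML over-expressors on each chromosome, read from the gene ID (horizontal axis). Chromosome 9 has 15 higher and 6 lower genes, whereas chromosome 1 has 4 higher and 33 lower.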

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

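The threshold of 0.1, the minimum mean level and the lists at an adjusted p under 0.05 and all chromosome counts were chosen after seeing the data. The choice of threshold moved the counts most. At an adjusted p under 0.01, 94 genes remained past the threshold (23 higher and 71 lower), against 203 (43 and 160) at 0.05. With the whole table, at 0.1, there were 318, of which 79 were higher. A minimum absolute log2 fold change of 1 left 188 genes, and a minimum mean level of 1 on the log2 CPM scale left 195. Of the 63 genes named by rule, 49 had an adjusted p under 0.05 and 33 one under 0.01. Over 12 lists of at least 3 members, 29 alternatives could be computed, and 28 had the same majority of higher or lower members. Each alternative kept a part of the same rows, so a list with all members in 1 direction could not change its majority. For such lists the count is no check. The cell wall list went from 71.4% lower to 100% lower when members were taken by ID or symbol only, because fewer genes entered it. The exception to the shared majority was the redox list, with 1 higher and 1 lower gene at an adjusted p under 0.05. The chromosome 9 rows were 28.6% lower in the whole table and 41.7% lower at an adjusted p under 0.05.

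Leaving out an over-expressing line, other normalizations, other pseudocounts, filters on counts and another count test were planned and not run, because the table gives 1 value per gene. No paired analysis was possible because wild type had a single library. Depth could not be weighed, since library totals were not used here. The smallest listed change was 2.22 on the log2 scale at mean levels under 1 on the log2 CPM scale, 1.60 at 1 to 2, 1.30 at 2 to 3 and 0.857 at 6 to 7. All of these were lower genes. Among higher genes the smallest were 6.41, 2.17, 1.93 and 0.93 in the same ranges. These limits bound what the authors' deposited table lists, and they differ by direction.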

Other observations

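All tests and gene groups of this part were chosen after the values were seen. All genes of a group of 37 for spindle, chromosome condensation and cell plate were lower in the authors' deposited table, 28 at an adjusted p under 0.05, with a median log2 fold change of -1.52. GIP1, described as an AtGCP3 interacting protein, was left out of the group and was listed higher at 1.35 (Potri.016G034200, adjusted p 0.0566, the authors' deposited table). As the group was put together from the table, its direction is no independent evidence, and 6 of its genes are also in the fixed cell cycle list. It includes the homologue of KNOLLE (SYP111, the syntaxin of the cell plate, -1.69), 2 homologues of NACK1 (-1.78 and -1.75), MAP65-5 (-1.62), EB1C (-1.59), 2 homologues of topoisomerase II (-1.58 and -1.48) and the condensin subunit SMC2 (-1.56 and -1.35), all values from the authors' deposited table. MYB3R1, a factor of mitotic gene expression, fell by 1.21 (Potri.006G241700, adjusted p 0.0407, authors' deposited table). In a group of chromatin regulators chosen in the same way, 18 of 19 were lower in the authors' deposited table, among them IBM1, a histone demethylase linked to gene body methylation (-1.31 and -1.07), and the remodeller SYD (-1.81, -1.66 and -1.11).

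The highest mean level in the authors' deposited table, 9.85 on the log2 CPM scale, belonged to a higher gene described as a phosphorylase superfamily protein (Potri.013G100700, 1.32, adjusted p 0.000769).

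By ID, 15 of the 21 listed genes of chromosome 9 were higher, whereas a library-wide technical difference, such as in RNA integrity or transcript length, would spread over the chromosomes, and 0 of 10000 random assignments of direction gave such an excess on any chromosome. Matched on level, 0 of 10000 gave as many on chromosome 9. The direction was thus not spread evenly over the chromosomes, but the same count had picked out chromosome 9 and measures neither RNA integrity nor length. Whether listed genes of chromosome 9 differ in length was not tested, so such a difference is not excluded. A candidate explanation is an extra copy of part of chromosome 9 in the over-expressors, or a missing one in the wild-type plants. The SD of the log2 fold changes of the 15 higher genes was 0.119, against 2.23 for 16 higher genes of other chromosomes in the same level range, but 11 of those 16 lay in the same range of folds, just above the listing limit. In the ID span of the 15 genes, 4 of the 19 listed genes were lower, and genes of the span that are not in the table would be needed to decide.

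The lower cell cycle genes may reflect fewer dividing cells in the over-expressing apices, or loss of long transcripts in those libraries, and the table decides neither. Replication and histone genes had a median log2 fold change of -1.06 over 10 genes, and mitosis genes one of -1.52, but the table holds only genes past the listing limit, 75.2% of them lower, so a median below 0 says little. With 1 wild-type library, a difference of genotype and one of this single sample cannot be told apart. Histone genes, which are short, had a median of -1.10 with 7 of 8 lower, 4 of them and the higher one at an adjusted p under 0.05, but random lists of the table gave similar values (percentile 26.1 for the share higher and 48.9 for the median), so they do not exclude a loss of long transcripts. Of genes with best hits known as very large proteins 30 of 30 were lower (percentile 0 for the share higher and 0.26 for the median). These genes were picked after their values were seen, so neither the count nor the percentiles are independent evidence of a length pattern. They do not exclude one either, and transcript lengths were not used here.

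The rows with plastid-encoded best hits sit in 2 runs of neighbouring IDs on chromosomes 13 and 11. All 7 listed genes of these runs were higher, by 2.05 to 5.88 on the log2 scale, 5 have no best hit, and 3 of the 5 lowest p-values of the authors' deposited table are theirs. Plastid RNA carried into the libraries in unequal amounts could give such rows if the assembly holds plastid sequence there. Both rows with plastid-encoded best hits (2 of 2) were higher, and read sequences or counts would be needed to decide.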
